A study of Mus musculus with 10 samples.

How the data were processed

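Single-nucleus RNA sequencing of mouse heart was performed in 10 libraries, 5 from mice given angiotensin II with vehicle and 5 from mice given angiotensin II with BPF, and each library was assigned to its group and replicate number from the submitters' labels. Per the labels' protocols, the mice were female C57BL/6, called germ-free and also kept under specific-pathogen-free conditions, nuclei were isolated from the heart in a lysis buffer and cleaned of debris, and libraries were made with the 10x Genomics 3' kit and sequenced on an Illumina NovaSeq instrument. The labels call the libraries biological replicates and give no sequencing batch or date. The deposited files hold raw UMI counts per gene and barcode, made by the authors with Cell Ranger 9.01 against mm10 per the submitters' processing notes; the annotation release and whether intronic reads were counted are not given in the sources used here. Values in each matrix were whole numbers, per the file headers and by inspection. The barcode with the fewest UMIs held 500 or 501 in 9 libraries and 1117 in vehicle replicate 2, so the deposited barcodes had already been selected. A UMI is a molecular tag, so counts are molecules and not reads.

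All 55357 genes listed were read. Gene positions, lengths and GC content came from the GENCODE M21 annotation of GRCm38, the assembly also called mm10, in which 52081 of the listed genes were matched by identifier and 49847 of them carried the same symbol. Among 134 named genes, 133 had a position, 34 overlapped another gene on the same strand and 53 one on the opposite strand, and the report says so for called genes, since use of strand in the counting is not given in the sources used here. Barcodes shared between libraries were counted over 45 pairs. The number relative to the median pair ran from 0.759 to 1.30 and no pair shared more than 119 barcodes, so no library was treated as deposited more than once.

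Nuclei with at least 500 UMIs, at least 300 genes and at most 10% mitochondrial UMIs (156883 of 160695 barcodes) were clustered together with scanpy 1.11.5 (Python 3.11.15, anndata 0.12.19, leidenalg 0.10.2): 3000 variable genes with the library as batch, counts scaled to 10000 per nucleus and log-transformed, 30 principal components, 15 neighbours and Leiden resolution 1, without batch integration. Doublets were called per library with Scrublet at an assumed rate of 0.4% per 1000 nuclei and its automatic threshold. In vehicle replicate 2 the automatic threshold of 0.721 marked 0% of nuclei, so a fixed score of 0.25 was used, which marked 3.73%. For the tests, nuclei with more than 5% mitochondrial UMIs and 17828 called doublets were left out, which kept 129800 nuclei. No correction for free RNA was applied; an alternative left out genes with a level under 0.1 of that in another class.

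The 31 clusters were named from marker lists fixed beforehand. A marker was counted for a cluster when at least 5% of its nuclei had a UMI of it and the level was at least 2 times that of the median cluster, at least 3 markers were needed, and 10 clusters with at least 40% called doublets stayed unnamed as mixed (7983 retained nuclei). The remaining 121817 nuclei fell into 13 classes, called "-like" because their identity rests on markers, with T, NK and B cell markers giving the lymphocyte-like class. These naming thresholds, including the doublet percentage, were set after the files were read. Markers of B cells, neutrophils, dendritic cells, mast cells, erythroid cells, adipocytes and skeletal muscle were also listed, and their summed levels are given under the other observations.

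Shares of retained nuclei and library quality measures were compared with two-sided exact permutation tests of the difference of means over all assignments of 5 and 5 libraries, adjusted by Benjamini-Hochberg. Nuclei are not replicates, so raw counts were summed per library and class in each class with at least 20 nuclei in every library (12 of 13; the adipocyte-like class was left out). Cardiomyocyte-like sums held 16995683 to 36957972 counts from 3554 to 6376 nuclei per library, fibroblast-like 2378543 to 9479065 from 1231 to 2525, vascular endothelial-like 3079124 to 14569075 from 1613 to 4858, macrophage-like 319680 to 2912331 from 180 to 811, and pericyte-like 487920 to 2830732 from 279 to 837. Sums were fitted with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3) with TMM factors and the package's expression filter, BPF minus vehicle, without covariates, two-sided, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. CPM values are counts scaled with TMM factors to a common total of the class's sum in each library, given as mean ± SD over 5 libraries, and log2 folds carry a standard error from the edgeR fit.

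Gene lists (32, for cardiac stress, contraction, calcium, matrix, inflammation, metabolism, stress responses, hormone and xenobiotic receptors and vascular biology) were tested with camera of limma 3.58.1 on voom values at a preset correlation of 0.01 in the 5 main classes, 160 tests adjusted together. Lists, markers, nucleus filters and the tests of genes, lists, shares and quality measures were chosen before the data were examined. Named genes followed a rule fixed then as well: in each main class the 10 higher and 10 lower genes with the smallest p among those passing with at least 5 counts per library on average, or the 5 in each direction with the smallest p where fewer than 5 passed; up to 4 members of each called list with the smallest p; up to 4 members per list and class that passed over all genes; up to 3 in each direction that passed in a smaller class; and always Nppa, Nppb, Myh7, Ankrd1, Postn, Col1a1, Col3a1, Agtr1a, Esr1, Esr2, Gper1, Esrrg, Xist and Ddx3y. The thresholds for naming clusters were set on the clusters themselves, and the doublet percentage for mixed clusters took the place of a planned rule on leading markers of 2 classes.

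The alternatives were DESeq2 1.42.0, RLE factors, no expression filter, leaving out each library, the replicate number as a block, median UMIs as a covariate, other limits on mitochondrial UMIs and UMIs per nucleus, doublets kept, Leiden resolution 0.5, naming each nucleus by marker score, equal numbers of nuclei, free RNA genes left out, estimated correlations and fry, and for shares a centred log ratio and an edgeR test of nuclei counts. Added after the data were seen were a correction for GC content, gene length and transcript length (each library's deviation fitted with natural splines of 4 degrees of freedom and entered as an offset), fits without BPF replicate 1 or without that library and vehicle replicate 2, shares of named nuclei alone, the exact test on Xist, 95% Fisher intervals of correlations and corrected counts for exchanged labels. The intervals entered after the correlations were known, and an explanation is argued against by a correlation only where the whole interval lies beyond the bound. The ratio of folds used on free RNA was already known when a level gap between classes was required for it to argue against that source, which left the source open. Correlations over the 10 libraries used 100000 permutations, and group labels were redrawn in 100 of 126 possible splits.

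The edgeR step was tested on simulated counts with the means and library sizes of each class and 200 changed genes, in which the libraries had no shared structure beyond the known changes. At a log2 fold of 1 it recovered 57.8% of changed genes for cardiomyocyte-like sums, 57.6% for fibroblast-like, 63.6% for vascular endothelial-like, 63.6% for macrophage-like and 75.8% for pericyte-like sums, over 17150, 14342, 14590, 10276 and 10671 genes. At a log2 fold of 0.5 recovery was 1.5, 6.0, 13.6, 13.6 and 22.7%, so small changes were mostly below what 5 libraries per group can show. Unchanged genes called numbered 13, 4, 6, 3 and 4. Other software was numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.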

Results

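Gene expression was measured in single nuclei from the hearts of 10 adult female C57BL/6 mice, all of which carried an osmotic pump delivering angiotensin II, a peptide hormone that raises blood pressure and drives cardiac remodelling. The pump ran for 14 days and released 400 ng/kg/min. In 5 of the mice, bisphenol F (BPF), an industrial replacement for bisphenol A with reported estrogenic activity, was also given by gavage at 50 µg/kg for 2 weeks before the pump and for 14 days with it. The other 5 mice received corn oil vehicle. The comparison asks which nuclei and which transcripts of the angiotensin II-treated heart differ when BPF is added. All libraries came from mice on angiotensin II, so the effect of angiotensin II itself was not measured.

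The vehicle libraries (replicates 1 to 5) held 83529637, 57059971, 67930582, 84506276 and 67982932 UMIs in 15990, 20071, 16574, 21024 and 11171 barcodes. The BPF libraries held 64284939, 58153227, 93175237, 76688191 and 63372877 UMIs in 16199, 15510, 19246, 12918 and 11992 barcodes. After filtering, 129800 of 160695 barcodes were retained, with a median of 3674 ± 1118 UMIs per nucleus (mean of library medians ± SD, n = 5) in the vehicle group and 3727 ± 687 in the BPF group. The median mitochondrial share was 1.66 ± 0.567% with vehicle and 1.19 ± 0.335% with BPF, and called doublets made up 9.85 ± 6.90% and 11.5 ± 6.14% of nuclei. None of 5 quality measures separated the groups in exact permutation tests (smallest exact p = 0.167, adjusted p = 0.833). Xist, transcribed from the inactive X chromosome of females, stood at 1025 ± 88.3 CPM (counts scaled to a common library total) with vehicle and 1274 ± 184 CPM with BPF (two-sided exact permutation p = 0.0476, n = 5 and 5). BPF replicates 2 to 5 lay at 1192 to 1417 CPM, above the vehicle libraries at 938 to 1160 CPM, and BPF replicate 1 lay at 986 CPM among them. The Y-linked Ddx3y had 7 counts in all 10.

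The retained nuclei fell into 13 named classes. Cardiomyocyte-like nuclei made up 37.4 ± 2.92% of nuclei with vehicle and 32.6 ± 2.62% with BPF. Vascular endothelial-like nuclei lay the other way, at 20.5 ± 7.07% and 28.4 ± 3.46%, as did fibroblast-like nuclei at 12.9 ± 3.33% and 15.7 ± 0.590%. Macrophage-like nuclei amounted to 3.28 ± 1.25% and 4.51 ± 0.849%, pericyte-like nuclei to 3.87 ± 1.47% and 4.97 ± 0.488%, and lymphocyte-like nuclei to 0.553 ± 0.372% and 0.923 ± 0.256%. In vehicle replicate 2, 34.9% of nuclei sat in clusters of mixed identity rich in doublets, against 0.779 to 2.38% in the other vehicle libraries, and its endothelial-like (9.30%), fibroblast-like (7.10%) and macrophage-like (1.04%) shares were the lowest of all libraries. Without it, the BPF minus vehicle difference in percentage points was 5.13 for vascular endothelial-like (7.93 with all libraries), 1.35 for fibroblast-like (2.79), 0.666 for macrophage-like (1.23) and 0.537 for pericyte-like nuclei (1.10). The group means of mixed nuclei were 8.23 ± 14.9% and 1.76 ± 1.54% (exact permutation p = 0.556). All these percentages count nuclei left after called doublets were removed. In vehicle replicate 2 doublets were called at a fixed score of 0.25, which marked 3.73% of nuclei. Automatic thresholds of 0.149 to 0.2 marked 4.71 to 20.27% in the other vehicle libraries. The mixed percentage of vehicle replicate 2, and its shares over the same nuclei, therefore rest on an unlike cut.

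Each share was tested with a two-sided exact permutation test over all assignments of 5 and 5 libraries, whose smallest possible p is 0.0079. The unadjusted exact p was 0.0238 for fibroblast-like, 0.0397 for cardiomyocyte-like and 0.0397 for vascular endothelial-like nuclei, and the adjusted exact p was 0.172 for each, so no share passed the threshold of 0.05. With 13 classes, the adjusted exact p of a class that differs alone cannot go below 0.103. For macrophage-like and pericyte-like nuclei the adjusted exact p was 0.275. The remaining classes were atrial cardiomyocyte-like (3.46 against 2.52%), endocardial-like (5.93 against 5.46%), mesothelial-like (1.45 against 0.988%), lymphatic endothelial-like (1.08 against 0.906%), smooth muscle-like (0.620 against 0.667%), Schwann-like (0.323 against 0.399%) and adipocyte-like nuclei (0.429 against 0.188%). The cluster holding the largest part of the cardiomyocyte-like nuclei was cluster 5 in the vehicle group and cluster 6 in the BPF group. These clusters had medians of 2479 and 7200 UMIs per nucleus. Nuclei were pooled over libraries here, so this is not a comparison of libraries. Vehicle replicate 2 alone gave 5833 cardiomyocyte-like nuclei at a median of 2312 UMIs, against medians of 4751 to 8426.5 in the other vehicle libraries.

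**Figure D1:**
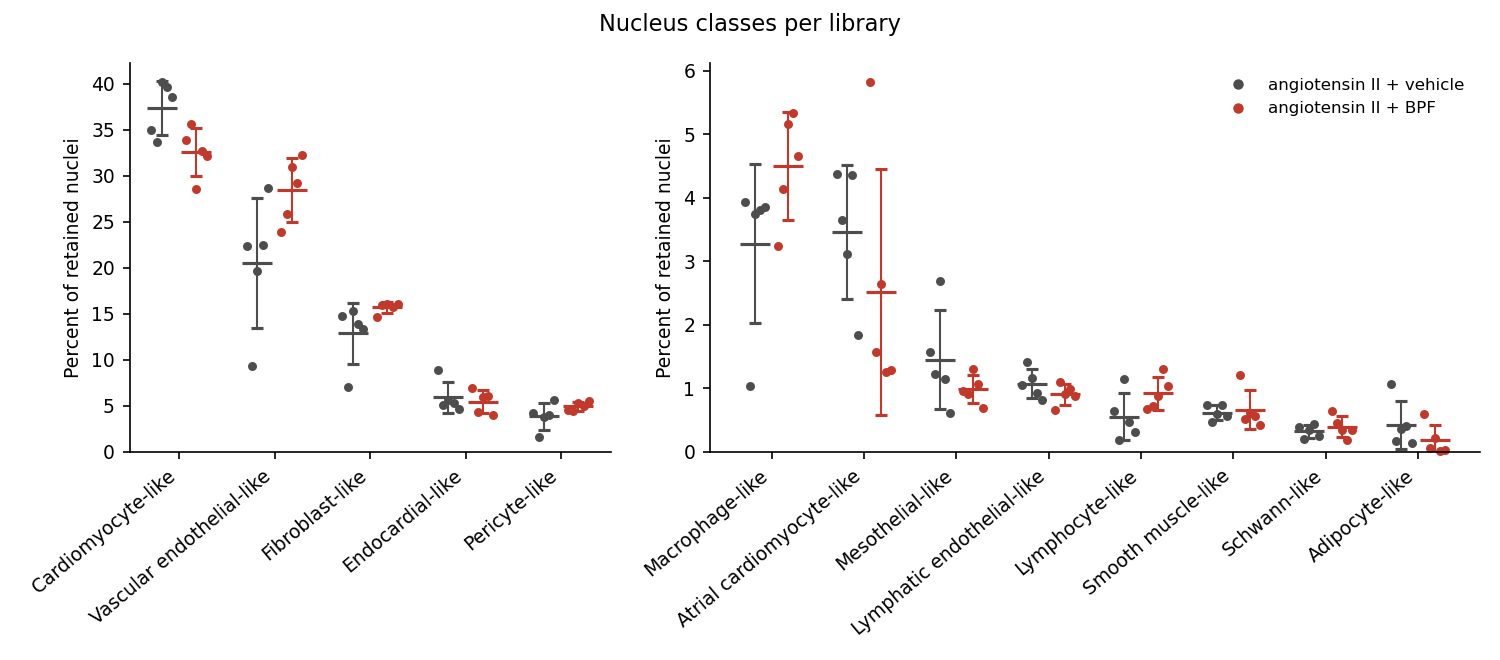
Percent of retained nuclei in each named class (linear axes), 1 point per library, with the mean and SD of 5 libraries per group as bars. Cardiomyocyte-like shares averaged 37.4% with vehicle and 32.6% with BPF, and 1 vehicle library lay lowest for endothelial-like (9.30%), fibroblast-like (7.10%) and macrophage-like (1.04%) nuclei.

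In cardiomyocyte-like nuclei, the list of stress and fetal genes was not called (camera adjusted p = 0.381, direction up), with 14 members above 0 and 11 below, 0 passing over all genes and 4 higher adjusted over the list alone. Nppa, which encodes atrial natriuretic peptide, averaged 275 ± 168 CPM with vehicle and 180 ± 63.0 CPM with BPF (log2 fold -0.61 ± 0.38 SE, edgeR adjusted p = 0.560, n = 5 and 5). Nppb, the B-type peptide, had a log2 fold of -0.37 ± 0.51, the fetal myosin Myh7 one of 0.06 ± 0.24 and the stretch-responsive Ankrd1 one of -0.05 ± 0.31 (edgeR adjusted p = 0.832, 0.953 and 0.965). The genes with the smallest p lay beyond the vehicle range in 4 or 5 of the BPF libraries but did not pass. Traf6, an adaptor of toll-like and interleukin-1 receptors, stood at 10.9 ± 2.39 and 26.7 ± 7.83 CPM (log2 fold 1.30 ± 0.23, edgeR adjusted p = 0.155), with 4 of 5 BPF libraries above all vehicle libraries. Pink1, a kinase that tags damaged mitochondria, stood at 19.2 ± 2.58 and 13.6 ± 1.42 CPM (adjusted p = 0.161), and the Polycomb gene Bmi1 at 8.70 ± 0.624 and 5.68 ± 0.875 CPM (adjusted p = 0.157), with all 5 BPF libraries below all vehicle libraries. Others on this side of the ranking were AW011738, BC023105, Eid2b and AY036118 on the higher side and Ybx1, Zfand5 and Gm38230 on the lower side, all with adjusted p between 0.155 and 0.161.

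Of 17391 genes tested in cardiomyocyte-like nuclei, edgeR called 0 higher and 0 lower, 2128 had an unadjusted p under 0.05, and DESeq2 called 329 higher and 25 lower. Without BPF replicate 1, edgeR called 482 higher and 92 lower, and without vehicle replicate 1 it called 62 higher and 0 lower.

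In fibroblast-like nuclei, collagen transcripts were lower on average in the BPF group without passing. Col3a1 averaged 1282 ± 671 CPM with vehicle and 687 ± 164 CPM with BPF (log2 fold -0.90 ± 0.34, edgeR adjusted p = 0.418), Col1a1 506 ± 264 and 318 ± 62.8 CPM (-0.67 ± 0.31, adjusted p = 0.586), and Postn, a matricellular protein of activated fibroblasts, 141 ± 108 and 89.7 ± 27.2 CPM (-0.65 ± 0.40, adjusted p = 0.734). Agtr1a, the receptor that binds angiotensin II, stood at 8.26 ± 1.67 and 9.03 ± 1.25 CPM (0.13 ± 0.18, adjusted p = 0.909). The smallest p belonged on the higher side to Fam207a, at 8.84 ± 1.13 and 16.7 ± 1.56 CPM with all 5 BPF libraries above the vehicle range (adjusted p = 0.163), and to Nme4, Polr1f, Gm11084 and AY036118. On the lower side it belonged to the matrix protease Adamts17 (3.96 ± 0.796 and 1.71 ± 0.709 CPM, adjusted p = 0.178), Xirp2, Scml2, Gm28905 and Gria3.

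For fibroblast-like nuclei, edgeR called 0 of 14593 genes in either direction, 1229 had an unadjusted p under 0.05, and DESeq2 called 161 higher and 5 lower. Without BPF replicate 1, edgeR called 187 higher and 3 lower.

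In vascular endothelial-like nuclei the genes with the smallest p had higher or lower means with BPF without passing. Ier2, an immediate early gene, stood at 16.9 ± 4.55 and 80.0 ± 36.9 CPM (log2 fold 2.24 ± 0.37, edgeR adjusted p = 0.105), with 4 of 5 BPF libraries above all vehicle libraries. Tm2d1 stood at 29.5 ± 2.85 and 58.4 ± 11.96 CPM (0.98 ± 0.15, adjusted p = 0.105, 5 of 5 libraries), and Crlf2, a subunit of the receptor for thymic stromal lymphopoietin, at 3.50 ± 1.12 and 27.3 ± 14.6 CPM (2.98 ± 0.47, adjusted p = 0.105). 4930426I24Rik and Gm10399 completed the higher side. Lower means were seen for the Rac regulator Chn1 (29.9 ± 6.18 and 18.3 ± 1.501 CPM, adjusted p = 0.105), the imprinted Peg3 (43.1 ± 9.70 and 25.9 ± 3.91 CPM, adjusted p = 0.109), the guanylate cyclase subunit Gucy1b1, Cpeb4 and Lrch2, in 5 of 5 BPF libraries each.

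Among 14784 genes of vascular endothelial-like nuclei, edgeR called 0 in either direction, 1760 had an unadjusted p under 0.05, and DESeq2 called 307 higher and 26 lower. Without BPF replicate 1 the edgeR count was 404 higher and 27 lower, and without vehicle replicate 1 it was 121 higher and 3 lower.

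In macrophage-like nuclei 4 genes rose with BPF and 0 fell, of 10482 tested with edgeR. Neurl3 (ENSMUSG00000047180; GRCm38 chromosome 1, 36264597 to 36274679), an E3 ubiquitin ligase gene, rose from 57.4 ± 5.81 to 125 ± 26.0 CPM (log2 fold 1.10 ± 0.16, edgeR adjusted p = 0.0306), and all 5 BPF libraries exceeded all vehicle libraries. The non-coding 2900052L18Rik (ENSMUSG00000043993; chromosome 11, 120229802 to 120231585) rose from 1.91 ± 1.20 to 15.4 ± 8.15 CPM (2.78 ± 0.45, adjusted p = 0.0393, 5 of 5 libraries). AY036118 (3.78 ± 0.59, adjusted p = 0.0362) has no position in the annotation used and is known to overlap ribosomal RNA sequence, and Gm11084 (3.06 ± 0.48, adjusted p = 0.0362) lies within Sp3 on the same strand and overlaps Sp3os on the other, so both levels are uncertain. Among genes that did not pass, Spp1, the osteopontin gene of activated macrophages, stood at 61.7 ± 112 and 3.64 ± 3.20 CPM (-4.22 ± 1.04, adjusted p = 0.193), and vehicle replicate 3 alone was at 261 CPM. Ednrb, an endothelin receptor, stood at 343 ± 58.3 and 228 ± 48.0 CPM (-0.59 ± 0.16, adjusted p = 0.255), and the coagulation factor gene F10, Atp6v0d2, Bmpr1a and Rai14 also had lower means. Ier2 (1.77 ± 0.33, adjusted p = 0.0634), Crlf2 (7.10 ± 3.27 and 55.6 ± 34.4 CPM, adjusted p = 0.0585) and Junb (1.87 ± 0.40, adjusted p = 0.126) had higher ones.

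The macrophage-like nuclei numbered 180 to 811 per library, with 319680 to 2912331 counts. The number of calls was 23 higher and 0 lower without vehicle replicate 1, 68 and 2 without BPF replicate 1, 7 and 0 without BPF replicate 2, 2 and 0 without BPF replicate 3, and 0 and 1 without vehicle replicate 3. It was 0 without vehicle replicates 2, 4 or 5 or BPF replicates 4 or 5, each left out alone, and DESeq2 called 35 higher and 2 lower on all 10. With edgeR it was also 0 with median UMIs as a covariate, with names by marker score and with equal numbers of nuclei. With GC content and length corrected 6 genes were called higher, 2 of them among the 4.

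With edgeR, pericyte-like nuclei had the most calls, with 43 genes that rose and 1 that fell with BPF of 10812 tested. DESeq2 made more calls in cardiomyocyte-like (354) than in pericyte-like nuclei (135). The edgeR count was 0 with median UMIs as a covariate, at Leiden resolution 0.5 and with names by marker score. It was 49 with free RNA genes left out, 43 of them among the 44 calls of the main fit. With equal numbers of nuclei it was 54, of which 23 were among the 44. With GC content and length corrected it was 49, of which 36 were among the 44. Ccn2 (ENSMUSG00000019997; chromosome 10, 24595442 to 24598683), which encodes connective tissue growth factor, rose from 49.8 ± 11.5 to 134 ± 44.9 CPM (log2 fold 1.42 ± 0.22, edgeR adjusted p = 0.0369, 5 of 5 BPF libraries above all vehicle libraries). Pdgfa (ENSMUSG00000025856; chromosome 5, 138976014 to 138997370), a platelet-derived growth factor, rose from 18.1 ± 2.59 to 62.0 ± 29.6 CPM (1.80 ± 0.32, adjusted p = 0.0416, 4 of 5 libraries). Stress-induced transcripts were among the calls, with Ier2 (ENSMUSG00000053560; chromosome 8, 84661331 to 84662852) at 13.2 ± 4.97 and 54.2 ± 22.1 CPM (1.96 ± 0.33, adjusted p = 0.0381) and the small heat shock protein gene Hspb1 at 4.03 ± 2.44 and 54.6 ± 49.1 CPM (3.78 ± 0.75, adjusted p = 0.0465). Respiratory chain subunits Cox5a (28.3 ± 15.4 and 131 ± 61.7 CPM, 2.25 ± 0.41, adjusted p = 0.0416) and Cyc1 (1.55 ± 0.31, adjusted p = 0.0465) rose, the 2 members of the oxidative phosphorylation list to pass there, while 26 of its 42 members lay below 0 and the list was not called (median log2 fold -0.04, mean 0.05, camera direction up, adjusted p = 0.984). Higher levels were also called for the class I antigen gene H2-D1 (1.09 ± 0.22, adjusted p = 0.0465), Rps2, Tigd2, Tmem259, Mrps34, Ccdc85b, AY036118 and Gm11084. The gene that fell was Mmp16 (ENSMUSG00000028226; chromosome 4, 17852893 to 18119145), a membrane-bound matrix metalloproteinase, from 22.6 ± 4.63 to 9.07 ± 3.44 CPM (-1.33 ± 0.28, adjusted p = 0.0493, 5 of 5 libraries below all vehicle libraries). Agtr1a, the angiotensin receptor gene, stood at 174 ± 29.1 and 169 ± 20.8 CPM (-0.03 ± 0.13, adjusted p = 0.967).

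For most of the named genes that passed, BPF replicate 1 lay within the vehicle range: Cox5a was at 27.4 CPM there, against 127 to 188 CPM in the other BPF libraries and 16.4 to 51.0 CPM with vehicle. H2-D1 and Rps2 share sequence with related genes or pseudogenes, Rps2 and Mrps34 overlap Snora64 and Nme3 on their strands, and Gm11084 overlaps Sp3, so their counts are uncertain. Annotated genes on the opposite strand overlap Ccn2, Pdgfa, Cox5a, Mmp16, Ccdc85b, Tmem259, Rps2, Mrps34 and Gm11084, and these counts are uncertain to the extent that reads were counted without regard to strand. The calls numbered 289 higher and 33 lower without BPF replicate 1, 115 and 0 without vehicle replicate 1, and 14 without BPF replicate 3. They were 0 when any 1 of vehicle replicates 2, 3, 4 or 5 or BPF replicates 2, 4 or 5 was left out, and DESeq2 called 129 higher and 6 lower on all 10.

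**Figure D2:**
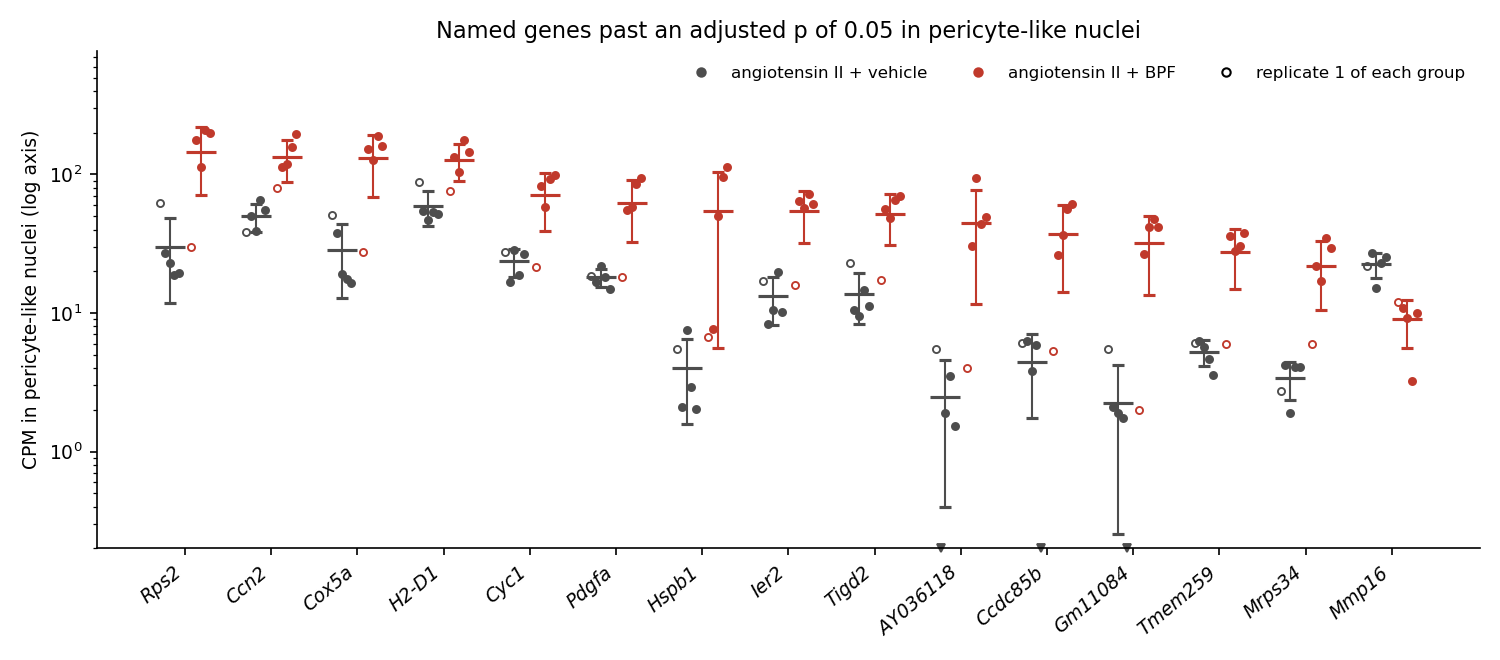
CPM (log axis) of the 15 named genes that passed in pericyte-like nuclei, 1 point per library, with bars for the mean and SD of 5 libraries per group, open points for replicate 1 of each group, and triangles at the foot of the axis for 3 values of 0. Mmp16 is the gene that fell, and for Cox5a the open BPF point (27.4 CPM) lies among the vehicle points.

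The 7 smaller classes (atrial cardiomyocyte-like, endocardial-like, lymphatic endothelial-like, lymphocyte-like, mesothelial-like, Schwann-like and smooth muscle-like nuclei) yielded 0 edgeR calls, with 3167 unadjusted p under 0.05 over all 7, and DESeq2 called 98 higher and 6 lower. Without BPF replicate 1, edgeR called 156 higher and 6 lower, and without vehicle replicate 1 it called 15 higher. Leaving out BPF replicate 3 gave 5 calls, BPF replicate 4 gave 3, and vehicle replicate 2, vehicle replicate 3, vehicle replicate 5 or BPF replicate 2 gave 1 each.

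Receptors through which bisphenols are reported to act were followed in the class with their highest count. Esr1, the estrogen receptor alpha gene, stood at 54.1 ± 12.8 and 55.4 ± 8.90 CPM in fibroblast-like nuclei (log2 fold 0.03 ± 0.17, edgeR adjusted p = 0.985). Esr2 in atrial cardiomyocyte-like nuclei had a log2 fold of -0.33 ± 0.50 (adjusted p = 0.925) at 214 counts in all. Gper1, a membrane estrogen receptor, stood at 26.0 ± 6.23 and 34.4 ± 9.14 CPM in pericyte-like nuclei (0.40 ± 0.21, adjusted p = 0.503), and the estrogen-related receptor Esrrg had a log2 fold of -0.09 ± 0.11 (adjusted p = 0.804) in cardiomyocyte-like nuclei. None passed.

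The gene calls grew most when 1 BPF library was left out. Over the 5 main classes, edgeR made 48 calls with all 10 libraries, 1587 without BPF replicate 1 and 324 without vehicle replicate 1, and between 0 and 16 without any other library. The genes higher without BPF replicate 1 numbered 757 across the main classes, and 43 of them were called in all 5 main classes. They were short and rich in G and C: in pericyte-like nuclei their median GC content was 54.5% against 49.7% of all genes tested, and their median gene length 8.32 against 26.0 kb. In cardiomyocyte-like nuclei these values were 53.4 against 49.2% and 8.60 against 18.9 kb.

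**Figure D3:**
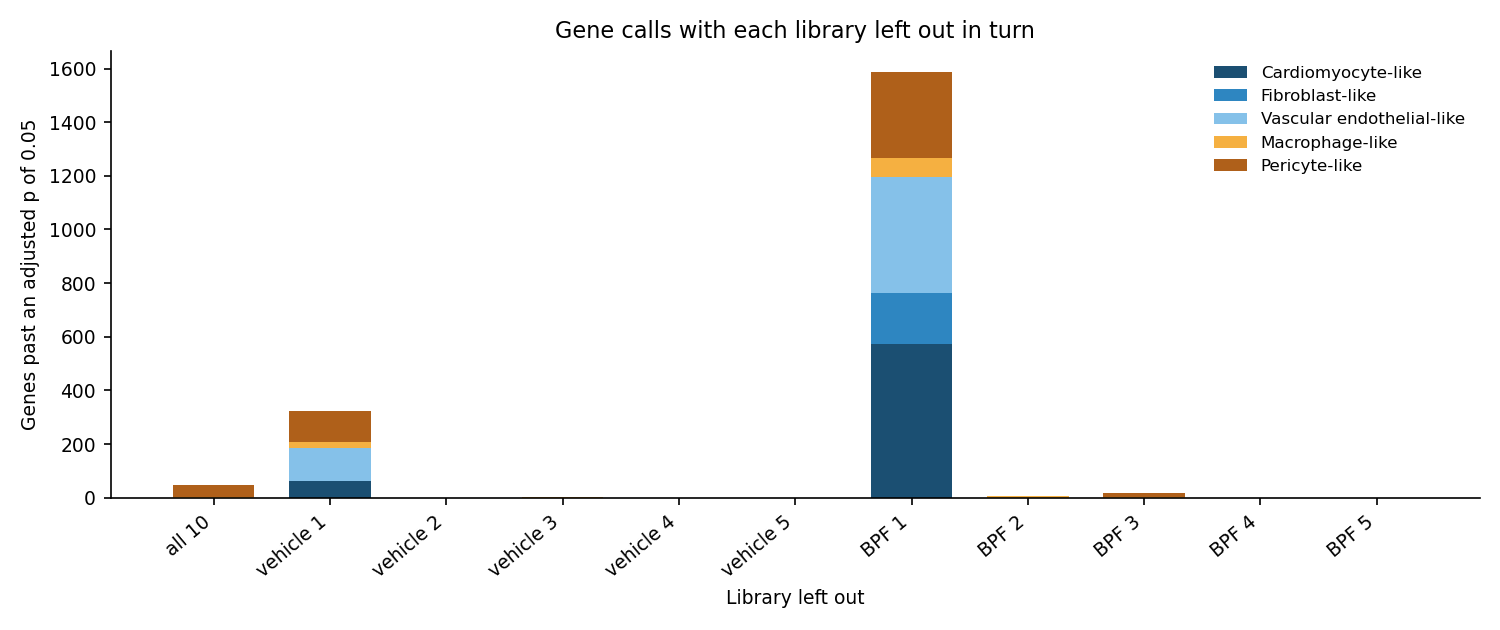
Number of genes past an edgeR adjusted p of 0.05 (linear axis) over the 5 main classes, stacked by class, with all 10 libraries and with each library left out in turn. The total is 48 with all libraries, 1587 without BPF replicate 1 and 324 without vehicle replicate 1.

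Gene lists fixed in advance were tested in the 5 main classes with camera of limma at a preset correlation, giving 15 lists called higher and 18 called lower of 160 tests. With a correlation estimated from the data 0 were called, the adjusted p = 0.909 with an estimated correlation for every one of the 33, and the directional test fry called 0 (smallest adjusted p = 0.374). Of the 33 calls, 8 held whichever library was left out. The fewest, 19, were kept without vehicle replicate 3, and 21 were kept without vehicle replicate 2, 23 without vehicle replicate 4, 26 without BPF replicate 4, 27 without BPF replicate 1, 27 without BPF replicate 5 and 30 or 31 without each of the others. For each call that was lost, the paragraphs below name 1 library whose absence ended it, and some calls were also lost without other libraries. Removing each library's trend on GC content and length left 17 calls, 15 of them among the 33. Among 100 of the 126 splits of the libraries into 5 and 5, the median number of list calls was 37. In 62 of these splits, the labelled one included, at least 33 lists were called. The number of list calls thus does not set the labelled groups apart from other splits.

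Inflammatory and antigen presentation genes were called higher. The list of cytokines, chemokines and NF-kB targets was called in vascular endothelial-like nuclei (median log2 fold 0.40, 18 of 22 members above 0, camera adjusted p = 0.00034; adjusted p = 0.909 with an estimated correlation). There 0 members passed over all genes and 6 passed when adjusted over the list alone, including the adhesion molecule gene Icam1 (34.4 ± 5.86 and 50.1 ± 8.24 CPM), the NF-kB inhibitor gene Nfkbia (336 ± 49.7 and 498 ± 96.8 CPM) and the neutrophil chemoattractants Cxcl1 and Cxcl2. In fibroblast-like nuclei (camera adjusted p = 0.0471) 1 member, the chemokine gene Cxcl14, and in pericyte-like nuclei (0.0499) 2 members, Nfkbia and Cxcl1, were higher adjusted over the list alone. Those calls were lost without vehicle replicate 4 (0.267) and BPF replicate 3 (0.329), and with GC content and length trends removed (0.111 and 0.166). The MHC and antigen presentation list was called in all 5 main classes, with median log2 folds of 0.33 in vascular endothelial-like, 0.35 in fibroblast-like, 0.37 in macrophage-like, 0.24 in cardiomyocyte-like and 0.23 in pericyte-like nuclei, and an adjusted p = 0.909 with an estimated correlation. H2-D1 was the single member past the threshold adjusted over the list alone, in vascular endothelial-like, fibroblast-like and pericyte-like nuclei, and the single member to pass over all genes, in pericyte-like nuclei. The macrophage-like and pericyte-like calls were lost without BPF replicate 4 (camera adjusted p = 0.218 and 0.093) and the cardiomyocyte-like call without vehicle replicate 4 (0.0769). With GC content and length trends removed, the macrophage-like, cardiomyocyte-like and pericyte-like calls were lost (0.0799, 0.0799 and 0.282).

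The unfolded protein response list was called higher in macrophage-like (median log2 fold 0.25, camera adjusted p = 0.00159), vascular endothelial-like (0.21, 0.0023) and pericyte-like nuclei (0.25, 0.00634), with an adjusted p = 0.909 with an estimated correlation. No member passed over all genes, and 5, 9 and 6 members were higher adjusted over the list alone. Among these were the transcription factor gene Xbp1, at 30.5 ± 3.63 and 62.6 ± 30.4 CPM in vascular endothelial-like nuclei, the disulfide isomerase Pdia3 at 89.0 ± 26.5 and 176 ± 63.4 CPM there, and Creld2 at 4.32 ± 1.45 and 14.4 ± 9.87 CPM in macrophage-like nuclei. Immediate early and heat shock genes were called higher in pericyte-like (0.25, camera adjusted p = 0.0023), macrophage-like (0.22, 0.0033), vascular endothelial-like (0.22, 0.00537) and cardiomyocyte-like nuclei (0.16, 0.0341), again with an adjusted p = 0.909 with an estimated correlation. Ier2 and Hspb1 passed over all genes in pericyte-like nuclei, and with Junb they passed adjusted over the list alone in pericyte-like, vascular endothelial-like and cardiomyocyte-like nuclei. These calls were lost without vehicle replicate 4 in macrophage-like (0.0979), without vehicle replicate 3 in vascular endothelial-like (0.26) and without BPF replicate 5 in cardiomyocyte-like nuclei (0.173), and all 4 were lost once each library's trend on GC content and length was removed (0.0897, 0.0604, 0.126 and 0.191).

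Extracellular matrix genes were called lower in vascular endothelial-like (median log2 fold -0.34, 33 of 35 members below 0, camera adjusted p = 2.72e-05), fibroblast-like (-0.30, 40 of 44 members, 0.000728), cardiomyocyte-like (-0.33, 0.0102) and macrophage-like nuclei (-0.40, 0.0398), with an adjusted p = 0.909 with an estimated correlation. No member passed, either over all genes or adjusted over the list alone. Examples from vascular endothelial-like nuclei were the protease inhibitor gene Timp1 (2.19 ± 0.976 and 0.778 ± 0.276 CPM, edgeR adjusted p = 0.143) and the microfibril gene Mfap5 (36.8 ± 9.61 and 24.0 ± 5.98 CPM, adjusted p = 0.259). Without vehicle replicate 3 the fibroblast-like and macrophage-like calls were lost (camera adjusted p = 0.596 and 0.656), and without BPF replicate 1 the cardiomyocyte-like call was (0.14). The macrophage-like call was also lost with GC content and length trends removed (0.0799). Dcn, Col1a1, Col1a2 and Col3a1 of this list were also fibroblast markers used to name clusters. The list tests were not run with free RNA genes left out. Outside fibroblast-like nuclei, free RNA or uncalled doublets were therefore not told apart from lower levels in the nuclei themselves.

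Transcripts of the contractile apparatus, which belong to cardiomyocytes, were called lower in fibroblast-like (-0.47, camera adjusted p = 0.00034), macrophage-like (-0.42, 0.0023), vascular endothelial-like (-0.41, 0.0122) and pericyte-like nuclei (-0.37, 0.0353) and were not called in cardiomyocyte-like nuclei, with an adjusted p = 0.909 with an estimated correlation. In fibroblast-like nuclei the giant sarcomere protein gene Ttn stood at 431 ± 211 and 230 ± 45.1 CPM and Myh6 at 268 ± 111 and 167 ± 25.2 CPM, with 0 members passing over all genes or adjusted over the list alone. All 4 calls were lost without vehicle replicate 3 (0.0648, 0.246, 0.364 and 0.592). Cardiomyocyte-like nuclei supplied 56.8 ± 3.03% of the UMIs of the named classes with vehicle and 51.5 ± 2.52% with BPF (unadjusted exact permutation p = 0.0317). Nuclei of mixed clusters were left out of that total. Genes of calcium handling were called lower in fibroblast-like (-0.29, 0.00445) and macrophage-like nuclei (-0.34, 0.00804), with 0 members passing and an adjusted p = 0.909 with an estimated correlation. Both calls were lost without vehicle replicate 2 (0.0717 and 0.0529) and with GC content and length trends removed (0.0897 each).

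In macrophage-like nuclei, interferon response genes (-0.19, camera adjusted p = 0.0023), renin-angiotensin and natriuretic peptide genes (-0.41, 0.0164), cardiomyocyte stress genes (-0.49, 0.0271) and the recruited monocyte program (-0.26, 0.0471) were called lower, with an adjusted p = 0.909 with an estimated correlation. Adjusted over the list alone, 0 interferon genes, 2 renin-angiotensin genes (Ednrb and Nppa), 1 stress gene (Nppa) and 1 gene of the recruited monocyte program (Spp1) were lower. These calls were lost without vehicle replicate 1 (0.0537), vehicle replicate 3 (0.062 and 0.526) and BPF replicate 3 (0.363) in that order, and the renin-angiotensin and recruited monocyte calls with GC content and length trends removed (0.069 and 0.0604). Nppa is a cardiomyocyte transcript. The stress list was drawn up for cardiomyocytes but also holds genes such as Ccn2 and Hspb1, which were called in pericyte-like nuclei. The contractile list stood at a median log2 fold of -0.42 in the same macrophage-like nuclei. Smooth muscle contractility genes were called lower in fibroblast-like (-0.16, 0.00804) and vascular endothelial-like nuclei (-0.12, 0.0349), with Gucy1b1 as the 1 member lower adjusted over the list alone, in the latter. Growth factor and kinase genes were called lower in vascular endothelial-like (-0.11, 0.0197) and pericyte-like nuclei (-0.14, 0.0309), with 0 members passing. Both lists had an adjusted p = 0.909 with an estimated correlation. The contractility calls were lost without BPF replicate 4 (0.123) and BPF replicate 5 (0.204), and both kinase calls without vehicle replicate 4 (0.155 and 0.187). With GC content and length trends removed, all 4 were lost (0.0923 and 0.195 for contractility, 0.622 and 0.502 for kinases).

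**Figure D4:**
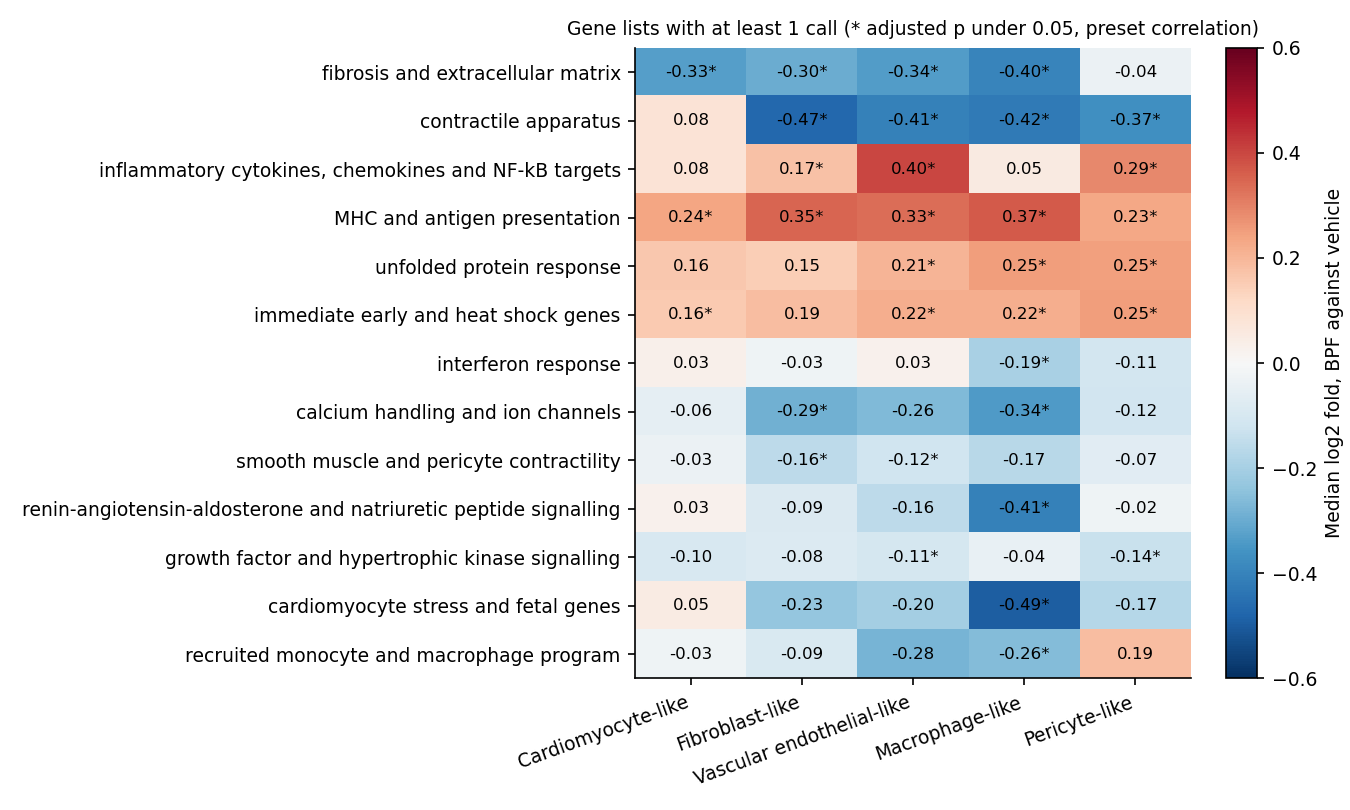
Median log2 fold (BPF against vehicle) of the members of each of the 13 lists called in at least 1 of the 5 main classes, as colours and numbers, with an asterisk where the camera adjusted p at the preset correlation was under 0.05. The extracellular matrix list is at -0.34 in vascular endothelial-like nuclei and the MHC list lies between 0.23 and 0.37 in the 5 classes.

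The other 19 lists were not called in any main class. Their smallest camera adjusted p was 0.0542 for fatty acid oxidation, 0.0888 for the cell cycle, 0.0942 for p53, apoptosis and senescence, 0.0975 for myofibroblast activation, 0.174 for the resident macrophage program and 0.245 for endothelial to mesenchymal transition. It was 0.293 for mitochondrially encoded and ribosomal protein transcripts, 0.336 for ferroptosis, 0.381 for each of glycolysis, angiogenesis and NRF2 targets, 0.384 for the inflammasome, 0.411 for cholesterol synthesis and 0.415 for xenobiotic metabolism. Oxidative phosphorylation (0.488), thyroid hormone and glucocorticoid response (0.566), the circadian clock (0.601), autophagy (0.634) and estrogen and androgen receptors with their targets (0.642) were farthest from the threshold.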

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

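The gap rule used here was set in advance and applied to every group of 5 libraries. Most of these groups are levels of named genes, many of which were picked by their p in the same data. A library was singled out when its gap to the nearest other library of its group exceeded 0.71 of the group's range (Dixon's limit for 5 values). This held in 34 of 422 groups of 5. Chance gives about 21.1 if the groups are independent, which they are not, since the same libraries recur. Vehicle replicate 2 accounted for 10 of the 34 and vehicle replicate 1 for 8. Vehicle replicate 3, BPF replicate 1 and BPF replicate 4 accounted for 4 each, BPF replicate 3 for 3 and vehicle replicate 4 for 1.

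Among class shares, vehicle replicate 2 had 34.9% of nuclei in mixed clusters (the other vehicle libraries 0.779 to 2.38%), 7.10% fibroblast-like nuclei (13.3 to 15.3%) and 1.04% macrophage-like nuclei (3.75 to 3.94%). Its doublets were called at a fixed score, unlike those of the other libraries. Vehicle replicate 1 had 1.08% adipocyte-like nuclei (0.139 to 0.404%) and 8.93% endocardial-like nuclei (4.69 to 5.66%). BPF replicate 1 was lowest of its group for fibroblast-like nuclei, at 14.65% against 15.75 to 16.06%, and highest for smooth muscle-like nuclei, at 1.21% against 0.425 to 0.611%.

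The mean log2 level of the contractile list in fibroblast-like nuclei was high in vehicle replicates 2 and 3 alike (6.29 and 6.02). By the gap rule, the muscle genes Atp2a2 and Cmya5 stood out in vehicle replicate 2 outside cardiomyocyte-like nuclei. The calcium pump gene Atp2a2 was at 343 CPM in fibroblast-like nuclei (214 to 248 in the rest of the group) and at 296 CPM in macrophage-like nuclei (189 to 208). Cmya5 was at 32.4 CPM in vascular endothelial-like nuclei (20.6 to 23.1). The pericyte marker Rgs5 reached 24.6 CPM in its fibroblast-like nuclei (5.03 to 9.05), where the class I antigen gene H2-Q7 was at 10.6 CPM (3.70 to 5.28). Its cardiomyocyte-like nuclei had 6.19 CPM of the matrix gene Fbln2 (2.38 to 3.28) and 8.88 CPM of H2-D1 (3.22 to 4.55). Further muscle values in macrophage-like or pericyte-like nuclei of BPF libraries, were Csrp3 at 81.6 CPM in replicate 4 (52.4 to 59.6), Ryr2 at 138 CPM in macrophage-like nuclei of replicate 3 (74.2 to 80.9) and Actc1 at 257 CPM in pericyte-like nuclei of replicate 4 (171 to 194).

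Vehicle replicate 1 was the highest of its group for AY036118 in cardiomyocyte-like (21.45 CPM against 4.44 to 8.42) and fibroblast-like nuclei (8.73 against 1.70 to 3.35), for Gm11084 in fibroblast-like (7.28 CPM against 2.07 to 3.53) and macrophage-like nuclei (12.2 against 2.29 to 5.12), and in pericyte-like nuclei for H2-D1 (87.7 CPM against 46.6 to 54.6) and Rps2 (62.5 against 18.7 to 27.3). BPF replicate 1 was the lowest of its group for Gm11084 in macrophage-like nuclei (8.35 CPM against 51.6 to 61.3) and for Ier2 in pericyte-like nuclei (16.1 CPM against 56.9 to 72.8). For these genes each library differed from the rest of its group in the direction of the other group's mean. Vehicle replicate 1 did not reach the BPF levels everywhere: its 12.2 CPM of Gm11084 in macrophage-like nuclei lay far below the 51.6 to 61.3 CPM of BPF replicates 2 to 5.

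Macrophage-like nuclei of vehicle replicate 3 had 261 CPM of the osteopontin gene Spp1, against 3.15 to 30.3 CPM in the rest of the vehicle group. In the same library, Gper1 was at 37.1 CPM in pericyte-like nuclei (21.9 to 24.6), Scml2 at 5.47 CPM in fibroblast-like nuclei (8.49 to 9.66) and the chemokine gene Cxcl2 at 1.35 CPM in vascular endothelial-like nuclei (0.426 to 0.643). Single values elsewhere were Esrrg at 2157 CPM in cardiomyocyte-like nuclei of vehicle replicate 4 (1733 to 1791), and Nppb at 80.9 CPM in cardiomyocyte-like nuclei of BPF replicate 3 (184 to 214). Gm28905 was at 2.94 CPM in fibroblast-like nuclei of BPF replicate 3 (1.98 to 2.23), H2-Q7 at 23.8 CPM in fibroblast-like nuclei of BPF replicate 4 (4.54 to 9.24) and the adhesion molecule gene Icam1 at 64.7 CPM in its vascular endothelial-like nuclei (45.4 to 48.7).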

How the results depend on the processing

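The corrections for GC content and length, the fits with BPF replicate 1 or with it and vehicle replicate 2 left out by choice, the estimated correlation combined with other settings and the share of named nuclei alone were chosen after the data were seen, and the other alternatives were planned.

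Gene calls depended on the test, on the filter and on single libraries, and where no cause is given the cause was not tested. With edgeR, cardiomyocyte-like nuclei had 0 calls, and the range with each library left out was 0 to 574, fibroblast-like 0 (0 to 190), vascular endothelial-like 0 (0 to 431), macrophage-like 4 (0 to 70), pericyte-like 44 (0 to 322) and the 7 smaller classes 0 (0 to 162). The highest value of each range came without BPF replicate 1. DESeq2 gave 354, 166, 333, 37, 135 and 104 in that order, and no filter beyond 1 count, which tests more genes, gave 166, 152, 279, 229, 440 and 1106. With BPF replicate 1 left out and GC content and length corrected, the 5 main classes gave 358, 200, 317, 75 and 295, and with BPF replicate 1 and vehicle replicate 2 left out 238, 85, 235, 58 and 236. A limit of 1% mitochondrial UMIs gave 3 fibroblast-like, 66 vascular endothelial-like, 18 macrophage-like and 76 pericyte-like calls. Macrophage-like calls were 0 with median UMIs as a covariate, with names by marker score and with the same number of nuclei from each library. Pericyte-like calls were 0 with median UMIs as a covariate, with a limit of 10% mitochondrial UMIs, at Leiden resolution 0.5 and with names by marker score, and 10 with doublets kept. The unadjusted p and DESeq2 counts beside the main counts of 0 stand in the report.

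The replicate numbers did not pair the libraries: same-numbered libraries of the groups had correlations of deviations from -0.659 to 0.021, 0 of 25 were over 0.1, and 0 vehicle libraries correlated best with their own number. Some best partners under other numbers recurred in all 5 main classes. These were vehicle replicate 3 with BPF replicate 4 (0.366 to 0.649), vehicle 4 with BPF 3 (0.335 to 0.523) and vehicle 1 with BPF 5 (0.188 to 0.411). What these pairs share was not tested. With the replicate number as a block, macrophage-like calls numbered 0 and pericyte-like calls 2, both were 0 with the block and the GC content and length correction together, and 36 lists were called, 31 of them shared with the 33.

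For gene lists, 33 calls became 0 with an estimated correlation, 0 with fry, 0 with an estimated correlation under the block and 0 with an estimated correlation and BPF replicate 1 left out. They numbered 17 with GC content and length corrected, 14 with that correction and BPF replicate 1 left out, and 21 to 40 with each library left out.

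No class share passed in any setting, but 0.103 is the lowest adjusted exact p that a class differing alone can reach over 13 classes and sign flips within replicate numbers cannot go below an exact p of 0.0625, so the exact tests say little on stability; the edgeR test of nuclei counts gave a lowest adjusted p of 0.362. In direction, 241 alternative values kept their direction and 6 reversed. As BPF minus vehicle in percentage points, a limit of 1% mitochondrial UMIs turned endocardial-like nuclei from -0.469 to 1.30, lymphatic endothelial-like from -0.170 to 0.104 and mesothelial-like from -0.462 to 0.161, and marker scores turned smooth muscle-like nuclei from 0.0473 to -0.329. With each library left out, endocardial-like nuclei ranged from -0.844 to 0.281 and smooth muscle-like nuclei from -0.0884 to 0.108. Quality measures kept their direction in 53 alternative values and reversed in 7. With each library left out, the difference in median UMIs ranged from -306.1 to 411 (52.5 with all), in median genes from -36.5 to 188 (83.3), in nuclei retained from -1780.0 to 211 (-780.4) and in percent doublets from -0.147 to 4.25 (1.64).

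The 191 named gene values, 19 of them called, had 3160 alternative values, of which 2789 kept direction and side of the threshold, 171 fell below it, 183 passed it and 17 reversed. None of those that reversed was a called gene. Log2 folds that changed sign were Agtr1a in pericyte-like nuclei with the depth covariate (0.08; -0.09 to 0.05 with each library left out), Ankrd1 under the block (0.13; -0.23 to 0.41), Esrrg (0.04) and Myh7 (0.00; -0.12 to 0.17) with GC content and length corrected, Nppb under the block (0.01) and Esr1 in fibroblast-like nuclei (-0.07 to 0.15 with each library left out). Sums rested on few nuclei in some classes, with as few as 22 in a library for Schwann-like, 30 for lymphocyte-like, 47 for smooth muscle-like, 180 for macrophage-like and 279 for pericyte-like nuclei.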

Other observations

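The test of GC content and length on the strongest split and both tests on contractile transcripts were set before their results were seen, and the tests of summed markers, of compact GC-rich transcripts, of depth and mitochondrial percent and of the splits, the corrected exchanges of labels and the intervals of correlations were chosen after.

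Markers of cell types without a tested class of their own were summed over all nuclei of the named classes, as mean CPM ± SD of 5 libraries with vehicle and BPF and a two-sided exact permutation test adjusted over 7 lists. B cell markers stood at 29.6 ± 10.9 and 44.2 ± 5.79 CPM (exact p = 0.0397, adjusted 0.0926) and dendritic cell markers at 81.5 ± 9.82 and 98.3 ± 12.8 CPM (exact p = 0.0159, adjusted 0.0556). Neutrophil markers were at 7.21 ± 1.90 and 9.50 ± 2.47 CPM and mast cell markers at 5.00 ± 0.995 and 5.45 ± 1.42 CPM (adjusted exact p = 0.211 and 0.676). Adipocyte markers were at 80.7 ± 35.4 and 56.7 ± 12.3 CPM, erythroid markers, mainly globins, at 742 ± 852 and 435 ± 77.4 CPM, and skeletal muscle markers at 1.91 ± 0.245 and 2.43 ± 0.182 CPM (adjusted exact p = 0.211, 0.714 and 0.0556). None of the 7 passed after adjustment, and a list that differs alone cannot go below an adjusted exact p of 0.0556 with 7 lists and 5 libraries per group.

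Compact, GC-rich transcripts were higher in BPF replicates 2 to 5 than with vehicle and not in BPF replicate 1, whose median log2 difference from vehicle over the genes called without it was -0.05, 0.05, 0.00, 0.10 and 0.06 in cardiomyocyte-like, fibroblast-like, vascular endothelial-like, macrophage-like and pericyte-like nuclei. Removing each library's smooth trend on GC content and length left at least 0.787 of the median log2 fold in each main class. In these classes 295 of 482, 144 of 187, 256 of 404, 55 of 68 and 217 of 289 genes stayed called. The genes were picked for their folds in the same libraries, which favours a high remaining share. That share therefore does not decide whether such a trend was the whole cause. Over all genes tested, 318, 189, 278, 72 and 248 were called higher with the trend removed and BPF replicate 1 left out. A smooth trend as fitted here thus did not remove the calls. Such a trend may account for part of the pattern. The slope of levels on GC content was -0.069 in BPF replicate 1, 0.014 to 0.088 in BPF replicates 2 to 5 and -0.092 to 0.052 with vehicle. Free RNA from 1 source stays open: over 476 genes tested in all 5 classes, the fold in the class of highest level was 1.02 times (quartiles 0.820 to 1.23) that in the others, and 1.02 times over the 37 genes whose level there was at least 4-fold higher, which goes against an outside source for those genes alone, and no class was the highest for more than a share of 0.284, which goes against 1 source class only so far as levels differ, since RNA leaking from a class that itself differs gives about the same ratio. Exchanged labels stay open: 2 of 5 exchanges of BPF replicate 1 gave more calls in every main class, 2816 with vehicle replicate 3 and 2065 with vehicle replicate 1 against 48 as labelled, but with GC content and length corrected 297 and 1486 (300 with vehicle replicate 2) against 55, of which only vehicle replicate 1 gave more in every main class, and leaving out BPF replicate 1 already raises the calls, so these cannot be told apart from a mouse that responded less. A BPF effect that 1 mouse did not show may account for the pattern as well, and the design holds nothing that tests it apart from a wrong label.

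Among the 100 of 126 possible splits that were run, the strongest separation of the libraries did not follow the treatment. Vehicle replicates 2, 4 and 5 with BPF replicates 1 and 3 against the rest gave 5159 calls over the 5 main classes. That points to a structure of the samples other than the labelled groups. With trends on GC content and length removed the same split gave 1094 calls, 0.212 times as many, of which 858 were among those before, while the median size of the log2 fold of the genes called before went from 0.83 to 0.59, 0.72 to 0.42, 0.61 to 0.33, 0.86 to 0.55 and 0.62 to 0.33 in cardiomyocyte-like, fibroblast-like, vascular endothelial-like, macrophage-like and pericyte-like nuclei, so such trends could account for part of it. The gene length slope of the libraries had r = -0.493 with median UMIs per nucleus (permutation p = 0.15, adjusted 0.2; Spearman rho = -0.503, permutation p = 0.14, adjusted 0.19; r = -0.62 without the 2 libraries farthest in UMIs), which leaves depth open. With the mitochondrial percent it had r = -0.029 (permutation p = 0.94, adjusted 0.94; rho = 0.03, permutation p = 0.95, adjusted 0.95; r = -0.019 without the farthest 2), and since 10 libraries allow r from -0.647 to 0.612 (95% Fisher interval, added once r was known), cytoplasmic carry-over stays open. No biological explanation was tested, as the labels give no other grouping.

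The contractile apparatus list was called lower with BPF in 4 classes other than cardiomyocyte-like (adjusted p = 0.909 with an estimated correlation), and its mean log2 level in fibroblast-like nuclei was 6.29 and 6.02 in vehicle replicates 2 and 3 against 5.11 to 5.25 in the other vehicle libraries and 4.99 to 5.42 with BPF. RNA set free by cardiomyocytes is a candidate source. Doublets left uncalled were not told apart from it, and vehicle replicate 2 had 34.9% of its nuclei in mixed clusters rich in doublets. The level in fibroblast-like and in macrophage-like nuclei had r = 0.939 over the 10 libraries (permutation p = 0.00064, adjusted 0.0026 over 4 relations; rho = 0.721, permutation p = 0.023, adjusted 0.092), in line with free RNA, but r was 0.582 without vehicle replicates 2 and 3, so the relation rests on those libraries. The level in fibroblast-like nuclei had r = 0.674 with the percent of UMIs from cardiomyocyte-like nuclei (permutation p = 0.027, adjusted 0.054; rho = 0.552, permutation p = 0.11, adjusted 0.19; r = 0.596 without BPF replicate 3 and vehicle replicate 3), so a lower cardiomyocyte share stays open. A change of these transcripts in the other cells by BPF was not tested apart from these.

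Group labels were redrawn in 100 of the 126 splits of the libraries into 5 and 5. In cardiomyocyte-like, fibroblast-like and vascular endothelial-like nuclei and in the smaller classes edgeR made 0 calls as labelled, which all 100 splits reach by construction, so the count of splits says nothing there. The highest other split gave 1043, 1342, 2014 and 587 calls. For macrophage-like nuclei 7 splits reached the 4 calls (highest other 247), and for pericyte-like nuclei 5 reached the 44 (highest other 1054). For gene lists 62 reached the 33 (highest other 69, median 37). Each of these counts includes the labelled split. The macrophage-like and pericyte-like counts also include the exchanges of BPF replicate 1 with vehicle replicate 1, 2 or 3. Those splits keep BPF replicates 2 to 5 together and stay close to the labelled groups, which weakens the counts as a measure of chance. The 33 list calls lay below the median of 37, so their number does not set the labelled groups apart from other splits. Chance cannot be excluded for the macrophage-like or pericyte-like counts. The unadjusted p and DESeq2 counts that belong to the counts of 0 are 2128 and 354, 1229 and 166, 1760 and 333, and 3167 and 104.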
